A study of Drosophila melanogaster with 34 samples.

How the data were processed

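The labels describe ovarian somatic cells grown at 26 degrees and transfected with siRNA. ChIP used 3 µg of antibody and chromatin sonicated to about 300 bases, and libraries from ChIP DNA were sheared to about 200 bases, per the labels' protocols. Samples were grouped by assay and knockdown from the titles, which number the ChIP samples 1 to 3 and the ATAC samples 1 and 2.

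The authors deposited 11 tables with 1 value per transposon consensus and column. The deposited RNA, ATAC, ChIP and input values are RPKM, scaled by consensus length and library depth, and the deposited small RNA values are RPM, scaled by library depth alone. Neither unit is named in the sources used here, and both were deduced from the values: 1 whole-number length per transposon and 1 whole-number read total per column gave whole reads, within a tolerance of 0.05, for 3606 of 3606 nonzero values. Lengths were found for 128 of 129 transposons (186 to 14477 bp). The recovery does not see a factor common to reads and totals. It was tested on simulated data, where 29 of 29 read totals and 99.9% of reads came back. Which reads the totals count, and how reads that match several related families were counted, is not given in the sources used here, so values of closely related families are uncertain. Per the submitters' processing notes, RNA was processed with cutadapt, Bowtie2 2.0.6, TopHat2 2.0.7 and Cufflinks 2.1.1, ChIP, input and small RNA with cutadapt and Bowtie 1.0.1, and ATAC with cutadapt and MACS2, on build dm3, with no order or role stated. Whether ATAC reads were shifted for the transposase, and whether the single ATAC column per condition pools replicates, is not given there.

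For each comparison the log2 change was log2((knockdown + p)/(control + p)), where the pseudocount p was 0.1 of the median nonzero value of the table. It was 0.553 RPKM for RNA, 5.80 for ATAC, 4.51 to 13.2 for ChIP and 4.45 to 4.63 for input, and 8.10 RPM for small RNA. Such changes understate those of low transposons. ChIP values were first divided by the input of the same knockdown and sample number. The 25% of transposons with the lowest mean in a table, 33 of 129, were left out. The mean took in all columns, knockdowns included. A transposon low in the control is thus kept where a knockdown value is high, as for RNA of FROGGER (0.108 RPKM in the control, 31.6 in H1-KD). Counts of rises can include such transposons. Changes were counted at 2-fold for RNA and small RNA and at 1.5-fold for ChIP and ATAC. Counting intervals at 95% were exact (Clopper-Pearson) for ratios of 2 libraries and a normal approximation on the log scale for ChIP over input. They are on the ratio without pseudocount, so for low values the interval does not always hold the printed log2 change. PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error only. On simulated ATAC data for Piwi-KD (96 transposons), 20 of 20 changed transposons were recovered, 0 of 76 unchanged ones were called, and 92.7% of intervals held the true change.

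Lists of transposons were fixed before the data were examined, as were the alternatives, the planned tests and the rule for named transposons. For the piRNA-rich list only the rule was fixed, and its members were read from the control small RNA column, so its small RNA change is measured against the library that selected it. They are the OSC target list, the gypsy, mdg1, BEL/Pao and copia groups, jockey-clade and I-clade non-LTR elements, telomeric non-LTR elements, rDNA and R elements, DNA transposons, germline-dominant transposons, and the 20 transposons with most Piwi-bound small RNA in the control (piRNA-rich list). Names were matched to the tables by hand, and GYPSY2 and Gypsy2 are separate entries. The OSC target list had 15 measured members, of which TIRANT was left out by the filter. A list is described by its median log2 change, a counting interval from 1000 Poisson draws, and the number of 10000 random lists of the same size, matched on mean level in 6 bins, with a median as extreme. The mean level was taken over all columns of a table, knockdowns included, so lists were not matched on their control level. Random lists were drawn from all kept transposons, and members of the list itself could be drawn. Transposons named are the members of the OSC target list as a group with examples, and the 8 largest rises and 4 largest falls per comparison. Others are named where a count of 5 or fewer or a contrast calls for it, chosen after their values were seen.

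The design foresaw a test over 10 ATAC libraries. With 1 column per condition it could not be made, and the rule for comparisons without replicates was used in its place. Contrasts between knockdowns were added beside the planned comparisons, apart from ATAC in Piwi-KD against H1-KD, which was planned. For H1 ChIP, limma 3.58.1 was fitted in R 4.3.3 to log2 ChIP over input of 94 transposons in 3 control and 3 knockdown libraries, with 2 residual degrees of freedom, after the data were seen. Of 20 transposons simulated at a log2 change of -1 among 94, it recovered 18 in Piwi-KD, 19 in Mael-KD and 16 in HP1a-KD, with 0, 1 and 0 false calls. Simulated knockdown libraries had the spread of the controls. Smaller changes, such as those of the OSC target list, were not simulated, so the power to call them is not known. Whether samples came from separate cultures is not given in the sources used here, so its p-values measure only the spread between these samples, which can be technical. Correlations across transposons used 100000 permutations and Benjamini-Hochberg adjustment over 4 tests. Unchanged libraries against the shared controls were simulated 1000 times with Poisson counting error alone. They hold no spread between libraries, so a control that deviates for another reason is not covered. Alternatives were another pseudocount (smaller or larger), no filter or a stricter one, centring on the median transposon, ChIP without input, and the mean of 3 H1 ChIP controls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.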

Results

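RNA, chromatin proteins, chromatin accessibility and Piwi-bound small RNA were measured in ovarian somatic cells (OSC), a cultured Drosophila line of somatic follicle-type cells that holds a nuclear piRNA pathway and is described as free of germ cells. Cells received siRNA against Piwi, the nuclear PIWI protein guided by piRNAs, against the linker histone H1, against the heterochromatin protein HP1a, or against Maelstrom (Mael), a factor of transcriptional silencing by Piwi, and cells with siRNA against EGFP were the control. The 34 samples fell into 25 groups. They comprised 10 ATAC-seq samples, 6 of H1 ChIP-seq, 3 of H3K9me3 ChIP-seq, 3 of HP1a ChIP-seq, 7 of ChIP input, 3 of poly(A)+ RNA-seq and 2 of small RNA immunoprecipitated with Piwi. The 11 tables used here hold 29 columns over the same 129 transposon consensus sequences. RNA of the knockdown targets was not analysed here, so the labels of the knockdowns were not checked by it. A consensus stands for many genomic copies and has no single chromosome position.

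Read totals recovered from the values were 20625614 to 25544579 for RNA, 3381967 to 5674137 for ATAC, 1560307 to 4266312 for input, 2170354 to 4261323 for H1 ChIP, 2173189 to 2420008 for H3K9me3 ChIP, 2599638 to 3334184 for HP1a ChIP, and 6973985 to 7397276 for small RNA. Transposons took 14.9% of the control RNA reads, 25.9% after Piwi knockdown (Piwi-KD) and 26.9% after H1 knockdown (H1-KD). In the ATAC table they took 11.2% in the control, 25.6% in Piwi-KD, 15.4% in H1-KD, 19.1% in HP1a-KD and 20.7% in Mael-KD. Wilson 95% intervals of these shares were at most 0.119 percentage points wide. Each comparison rests on 1 column per condition, apart from 3 control libraries of H1 ChIP, so no spread between replicates was available and no p-value is given for a difference between conditions unless a test is named. Intervals are at 95% and cover counting error only. After a filter on low mean values over control and knockdown columns, 96 transposons were compared in each comparison.

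The comparison of Piwi-KD with control RNA asks which transposons Piwi represses in these cells. The 8 largest rises were all LTR elements of the OSC target list: DM297 stood at 728 RPKM in Piwi-KD against 8.18 in the control (log2 change 6.38), DM412 at 749 against 8.67 (6.35), GYPSY at 1662 against 36.2 (5.50) and MDG1 at 1164 against 33.8 (5.09). GYPSY5 (6.88), QUASIMODO (6.13), GTWIN (5.86) and TABOR (4.83) completed them. The lowest values relative to control belonged to MARINER2 and TC1-2, both DNA transposons, at -1.53 and -1.05, and to the BEL/Pao LTR elements DIVER and DIVER2, at -1.19 and -0.99. All 14 kept members of the OSC target list, LTR elements commonly named as Piwi targets in these cells, were higher, 11 of them at least 2-fold, with a median log2 change of 4.96 (interval 4.93 to 4.99). The list rests on what is commonly reported for these cells and is not independent evidence of its direction.

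Across the 96 transposons, 23 were at least 2-fold higher and 3 at least 2-fold lower, and the counting interval of each lay on the same side of 0. Of 10000 random lists matched on mean level over control and knockdown columns, 1 had a median at or above that of the OSC target list. The median transposon changed by 0.11, and relative to it the list median was 4.85. Among the other lists, the mdg1 group had a median of 4.14, the piRNA-rich list 3.09, the gypsy group 0.23, the jockey-clade and I-clade non-LTR elements 0.18, DNA transposons 0.05, germline-dominant transposons -0.02, rDNA and R elements -0.05, the BEL/Pao group -0.11, the copia group -0.13 and the 2 kept telomeric elements -0.63. GYPSY5 had 43 control reads, and its ratio without pseudocount had an interval of 8.10 to 9.00 on the log2 scale.

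**Figure D1:**
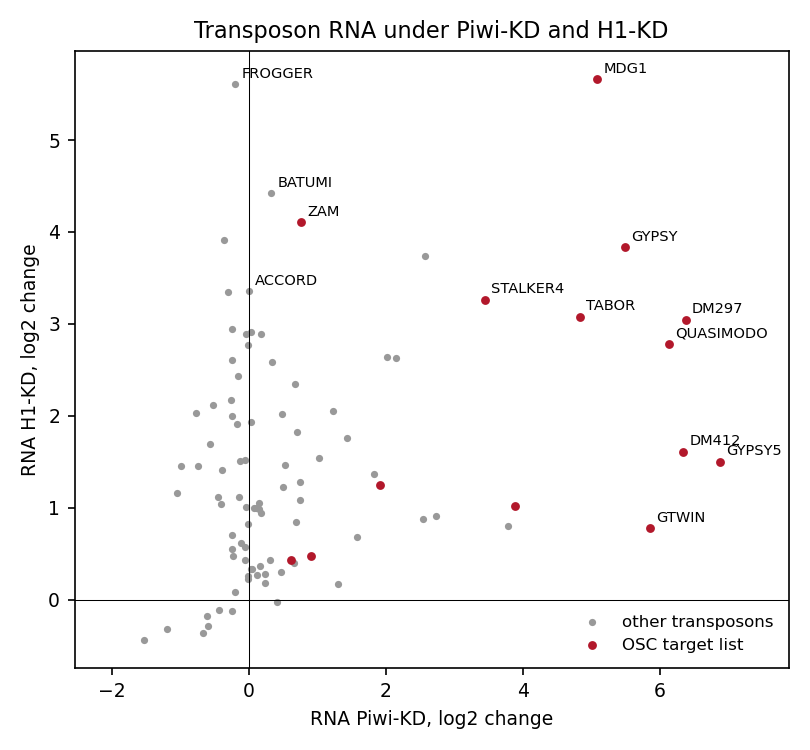
Log2 change of transposon RNA in H1-KD (vertical axis) against that in Piwi-KD (horizontal axis), both relative to the same control library, with 1 point per transposon among the 96 kept and the OSC target list in red. MDG1 was high in both knockdowns (5.09 and 5.67), whereas BATUMI and FROGGER lay high on the H1-KD axis alone.

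H1-KD was compared with the same control RNA to ask which transposons depend on the linker histone. MDG1 stood at 1742 RPKM against 33.8 (log2 change 5.67), ZAM at 66.1 against 3.32 (4.11) and GYPSY at 524 against 36.2 (3.83). Elements outside the OSC target list were also among the 8 largest: FROGGER, a copia-group element, at 31.6 against 0.108 RPKM (5.61, from 6 control reads), BATUMI of the BEL/Pao group at 71.6 against 2.81 (4.42), INVADER3 (3.91), the DNA transposon TRANSIB2 (3.74) and ACCORD (3.36, from 15 control reads). The 4 lowest were MARINER2 (-0.44), DIVER (-0.32) and the telomeric retrotransposons TART_B1 (-0.36) and TART (-0.29).

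The difference was broad: 88 of 96 transposons were higher, 56 at least 2-fold and none at least 2-fold lower, and the median transposon changed by 1.19. Relative to that median, MDG1 stood at 4.47, FROGGER at 4.41, BATUMI at 3.23, ZAM at 2.91 and GYPSY at 2.64, and the count became 24 higher and 11 lower. All 14 kept members of the OSC target list were higher than control, 11 at least 2-fold, with a median of 2.20 (interval 2.13 to 2.28). Relative to the median transposon the list median was 1.004, with 10 of the 14 members above it and 7 at least 2-fold, and 44 of 10000 random lists reached its median. Other list medians relative to the median transposon were 1.15 for the mdg1 group, 0.79 for jockey-clade and I-clade non-LTR elements, 0.52 for rDNA and R elements, 0.42 for the copia group, 0.26 for the piRNA-rich list, 0.17 for the BEL/Pao group, -0.15 for the gypsy group, -0.25 for DNA transposons, -0.91 for germline-dominant transposons and -1.52 for the telomeric elements. COPIA alone gave 2807529 of the control reads and 5290549 of the H1-KD reads, with a log2 change of 0.85.

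The knockdowns were also set against each other on RNA. Piwi-KD exceeded H1-KD for GYPSY5, at 94.2 against 1.73 RPKM, for GTWIN, at 76.9 against 1.74, for DM412, at 749 against 27.6, and for QUASIMODO, at 233 against 22.4. H1-KD exceeded Piwi-KD for FROGGER (log2 difference 5.81, from 1 read in Piwi-KD, interval 8.06 to 15.84 without pseudocount), INVADER3 (4.28), BATUMI (4.10), BURDOCK (3.65), ACCORD (3.35), ZAM (3.34), FW3 (3.18) and G5 (2.93). The OSC target list had a median difference of -1.71 for H1-KD minus Piwi-KD, and none of 10000 random lists was as low. The list names elements reported as Piwi targets, so it is not independent evidence of this direction either. In that difference 36 transposons were at least 2-fold higher and 12 lower, or 25 and 17 relative to a median of 0.73.

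Changes in the knockdowns shared 1 control library, so part of any overlap comes from it. Of the transposons at least 2-fold higher, 17 were common to Piwi-KD and H1-KD, where independent lists would share 13.4 and unchanged libraries against this control 0.01. Here and below, unchanged libraries differ by counting error alone. They cannot show how much overlap a deviating control library would give. The Spearman correlation was 0.22 and that of unchanged libraries 0.43. The latter ranks shared counting error alone, however small, so here and below it is no threshold for the observed correlation. The covariance was 0.713, against 0.007 for unchanged libraries.

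H1 ChIP over input was compared between each knockdown and the control of its sample number, to ask where H1 occupancy depends on Piwi, Mael or HP1a. In Piwi-KD the ratio to input fell short of the control by the largest margin at DM297 (0.64 against 1.16, log2 change -0.85), GYPSY (0.69 against 1.22, -0.82), MDG1 (0.74 against 1.28, -0.76) and DM412 (0.81 against 1.20, -0.55). The OSC target list had a median of -0.22 (interval -0.28 to -0.14), 11 of its 14 members were lower, and 3 of 10000 random lists were as low. Against the mean of the 3 controls the list median was -0.13. Of these members ZAM (0.24), IDEFIX (0.22) and STALKER4 (0.10) were higher.

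The 8 largest rises in H1 under Piwi-KD were POGON1 (1.34, from 8 control and 16 knockdown ChIP reads), GYPSY6A (1.12, from 17 and 21), PROTOP_B (0.59), STALKER3 (0.54), S (0.41), TRANSIB2 (0.34), GYPSY11 (0.34) and G7 (0.26). Most of the GYPSY6A value comes from input, since its 17 and 21 ChIP reads were from totals of 4056706 and 3699671. The POGON1 value rests on its control: log2 H1 over input of POGON1 was -1.73 in control 1, used here, and -0.21 and -0.17 in controls 2 and 3. Over all 96 transposons, 3 were at least 1.5-fold higher and 3 lower, with a median of 0.02.

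In Mael-KD the OSC target list had a median H1 change of -0.18 (interval -0.25 to -0.09), with GYPSY at -0.36, MDG1 at -0.32 and DM297 at -0.31, and 30 of 10000 random lists were as low. Without input the list median was -0.0814. No member passed 1.5-fold. The 4 lowest transposons were DM412B (-1.25, from 34 and 18 reads), PROTOP_B (-0.60, which became 0.07 without input), GYPSY11 (-0.56) and the DNA transposon TC1-2 (-0.56). DM412B and PROTOP_B were at least 1.5-fold lower, and the counting interval of PROTOP_B held 0. The 8 highest were G7 (0.33), FB4 (0.33), Chouto (0.24), PROTOP (0.20), ROOA (0.19), TC1 (0.16), BATUMI (0.16) and GYPSY4 (0.16).

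In HP1a-KD 77 of 96 transposons had lower H1 than control. All 14 kept members of the OSC target list were lower, with a median of -0.34 (interval -0.38 to -0.29). Relative to a median transposon of -0.11 the list stood at -0.23, and 2 of 10000 random lists were as low. QUASIMODO was lowest among the list members, at 0.69 against 1.15 over input (-0.71), followed by DM412 (-0.49) and DM297 (-0.48). DM412B (-1.15, from 74 and 28 reads), HELITRON1 (-1.03, from 22 and 12) and INVADER4 (-0.66) made up the rest of the 4 at least 1.5-fold lower, and none was as much higher. The 8 highest were POGON1 (0.16), R1 (0.16), MAX (0.14), G (0.14), DMRT1B (0.13), BATUMI (0.11), DMRT1A (0.11) and BEL (0.10), among which R1, DMRT1B and DMRT1A belong to the list of rDNA and R elements.

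The 3 control libraries gave list medians of 0.29, 0.14 and 0.18 for log2 H1 over input, or 0.20 ± 0.08 (SD, n = 3). Of the 14 list members, 10 were lower in all 3 knockdowns, as were 17 of 80 other transposons, or 8 of 80 after centring. A limma model of the knockdowns against the 3 controls, chosen after seeing the data, treats each lone knockdown library as varying like the controls and shares a standard error of 0.18 among transposons. With Benjamini-Hochberg adjustment limma called 4 transposons in Piwi-KD: DM297 (-0.77, adjusted p = 0.00439), GYPSY (-0.73, 0.00503), MDG1 (-0.65, 0.018) and STALKER3 (0.61, 0.0282). It called DM412B in Mael-KD (-1.09, adjusted p = 1.3e-06), and in HP1a-KD DM412B (-1.03, 6.7e-06), QUASIMODO (-0.75, 0.00346), POGON1 (0.69, 0.00703) and INVADER4 (-0.67, 0.00795). Without control 1, 2 or 3 the limma count was 23, 2 and 0 in Piwi-KD (51, 8 and 5 at an unadjusted p under 0.05), 6, 3 and 2 in HP1a-KD, and 1 each time in Mael-KD. Leaving out control 1, which has the sample number of Piwi-KD, gave 14 higher and 9 lower in Piwi-KD, and 6 lower and none higher in HP1a-KD, so the call of higher H1 at POGON1 was lost. The shared error understates the spread of some transposons called: the SD among controls was 0.24 for DM412B and 0.89 for POGON1, against a median of 0.11. After centring limma called 6 transposons in Piwi-KD, 0 in Mael-KD (9 at an unadjusted p under 0.05) and 1 in HP1a-KD. Without input limma called 0 in each knockdown (6, 1 and 1 at an unadjusted p under 0.05). Sample number was not modelled as a batch.

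H3K9me3 over input, a mark of heterochromatin, was lower at several OSC targets in Piwi-KD. DM297 stood at 1.16 against 4.72 over input (log2 change -1.98), MDG1 at 1.31 against 4.20 (-1.63), GYPSY at 2.21 against 6.75 (-1.60) and COPIA, which is outside the OSC target list, at 0.86 against 2.08 (-1.27). The OSC target list had a median of -0.55 (interval -0.65 to -0.46), with 7 members at least 1.5-fold lower and QUASIMODO 1.5-fold higher (0.64), and 15 of 10000 random lists were as low. The median transposon was at 0.32, and relative to it the list stood at -0.87 with 13 of 14 members below, ZAM, IDEFIX and STALKER4 among them although they were above control as deposited (0.06, 0.05 and 0.13). The remaining 7 of the 8 largest rises were GYPSY6A (1.33, from 11 and 19 reads), STALKER3 (0.90), BAGGINS1 (0.78), DIVER2 (0.72), G (0.68), R1 (0.65) and G5 (0.64). As deposited 13 transposons were at least 1.5-fold higher and 13 lower, and relative to the median transposon 1 was higher and 14 lower. The mdg1 group had a median of -0.95.

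H3K9me3 was also compared between H1-KD and control. BLOOD stood at 1.20 against 2.84 over input (-1.21), STALKER2 at 1.42 against 3.03 (-0.96) and MDG1 at 2.53 against 4.20 (-0.71), followed by the non-LTR element DOC6 (-0.64), whereas GYPSY was at 0.02 and DM297 at -0.28. The OSC target list had a median of -0.26 (interval -0.32 to -0.22), 3 members at least 1.5-fold lower, and 60 of 10000 random lists as low. The 8 largest rises were GYPSY6A (1.04, from 11 and 22 reads), G (0.60), S (0.56), HELITRON1 (0.55, from 13 and 11), BAGGINS1 (0.55), R1 (0.49), DMRT1A (0.48) and GTWIN (0.45). Counts past 1.5-fold were 2 higher and 6 lower, with a median of -0.01. Of the transposons past 1.5-fold lower, 5 were shared with Piwi-KD, where independent lists would share 0.81 and unchanged libraries 0.07, and the covariance was 0.125 against 0.007 for unchanged libraries (Spearman 0.59 against 0.42).

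HP1a over input followed a similar set of elements in Piwi-KD: GYPSY at 1.29 against 2.87 (-1.15), DM297 at 0.87 against 1.75 (-0.98), MDG1 at 1.04 against 1.90 (-0.84) and STALKER2 at 0.97 against 1.76 (-0.76). The median of the OSC target list was -0.33 (interval -0.43 to -0.28), 5 members were at least 1.5-fold lower, and 1 of 10000 random lists was as low. Over all transposons 2 were at least 1.5-fold higher and 6 lower, with a median of 0.05. The counting intervals of the 2 higher ones, GYPSY6A (0.91, from 19 and 20 reads) and POGON1 (0.90, from 7 and 10), held 0, and G7 (0.35), STALKER3 (0.35), PROTOP_B (0.34), TC1 (0.32), DOC3 (0.27) and S (0.26) completed the 8 largest rises. Nearly all of the GYPSY6A value comes from input, since its 19 and 20 ChIP reads were from totals of 2690165 and 2599638.

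In H1-KD, HP1a over input was lower at BLOOD (1.07 against 1.72, -0.68) and STALKER2 (1.09 against 1.76, -0.62), the 2 transposons past 1.5-fold, and then at Gypsy1 (-0.39) and MDG1 (-0.37). The largest rises were GTWIN (0.58), POGON1 (0.50, from 7 and 6 reads), G (0.50), G7 (0.48), Chouto (0.45), S (0.44), Chimpo (0.43) and BATUMI (0.41). For the OSC target list the median was 0.06 (interval 0.02 to 0.11), which became -0.06 relative to a median transposon of 0.12, and 587 of 10000 random lists were as low. Both transposons lower in H1-KD were also lower in Piwi-KD, where independent lists would share 0.13 and unchanged libraries 0.09. The covariance was 0.028 against 0.008 (Spearman 0.37 against 0.44).

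**Figure D2:**
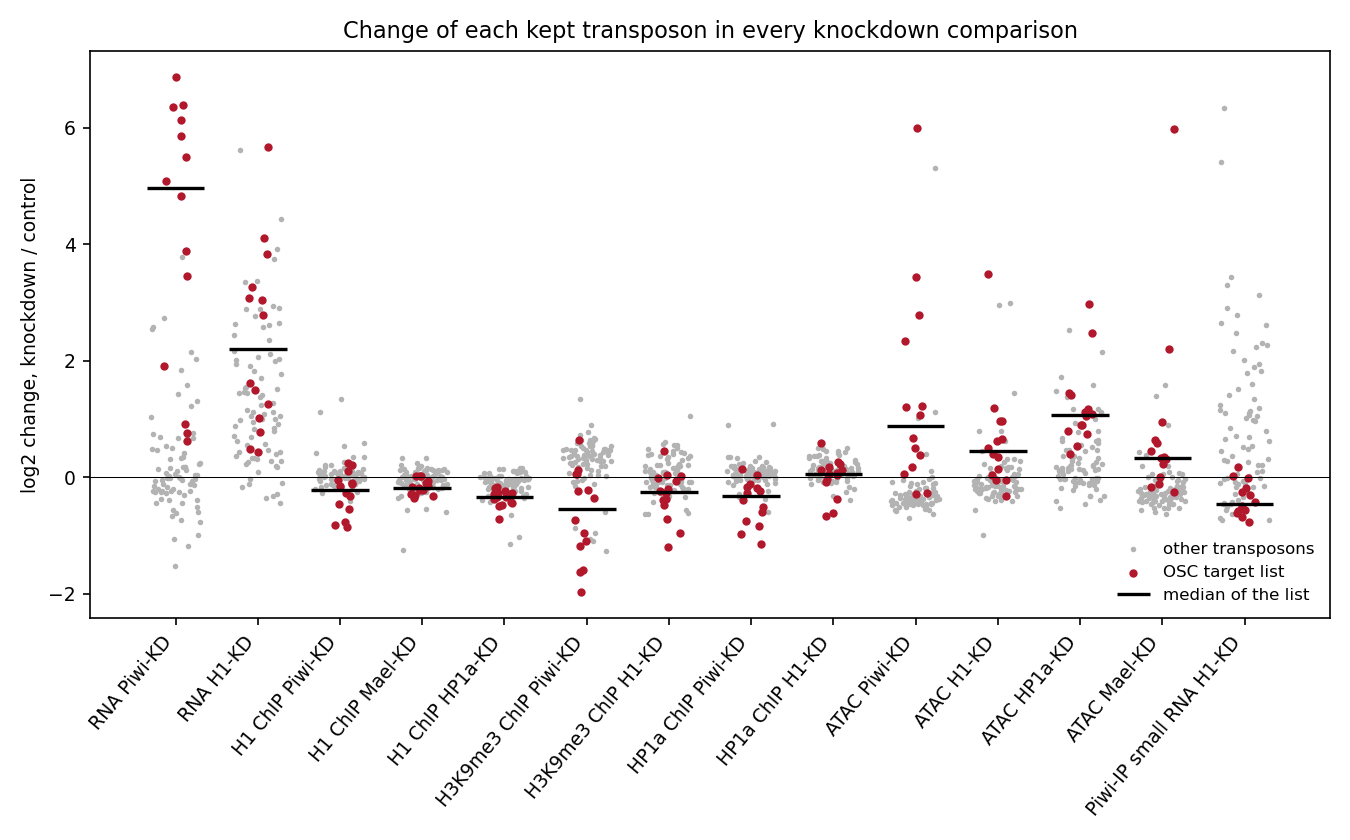
Log2 change of each kept transposon (96 points per column) in each comparison with control, with the OSC target list in red, its median as a black bar and other transposons in grey. Sideways scatter has no meaning. RNA values for the OSC target list reached 6.88 in Piwi-KD and 5.67 in H1-KD, whereas HP1a and H1 ChIP values stayed between -1.25 and 1.34.

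Chromatin accessibility by ATAC-seq was compared to ask whether loss of each factor opens transposon chromatin. The labels give 2 replicates per condition while the deposited values have 1 column per condition, so the planned test across replicates could not be made, and whether a column pools both replicates is not given in the sources used here. In Piwi-KD, DM297 stood at 12132 RPKM against 185 (log2 change 5.99), Gypsy2 at 2881 against 67.0 (5.31), GYPSY at 6848 against 630 (3.43), GTWIN at 235 against 29.0 (2.79) and QUASIMODO at 886 against 172 (2.33). DM176 (1.22), GYPSY5 (1.20) and DM412B (1.11) followed. Lowest were DMTOM1 (-0.71), BARI (-0.63), MARINER2 (-0.57) and GYPSY3 (-0.56). Members of the OSC target list had a median of 0.87 (interval 0.84 to 0.91), 8 members were at least 1.5-fold higher, and 1 of 10000 random lists reached it. The median transposon was at -0.32, so the list stood at 1.19 relative to it, with all 14 members above, ZAM (-0.30 as deposited) and STALKER4 (-0.26) included. Counts were 11 higher and 2 lower as deposited, and 14 and 0 relative to the median transposon. DM297, GYPSY and Gypsy2 took 453030, 271584 and 112523 of 5674137 reads in Piwi-KD. In the control they took 4124, 14883 and 1560 of 3381967. Values are scaled by depth, so such gains lower the values of other transposons, by an amount that was not estimated. The lowering also enters the contrasts of Piwi-KD with other knockdowns.

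In H1-KD the ATAC signal was also highest relative to control at DM297 (2146 RPKM, 3.49) and Gypsy2 (569, 2.98), and then at MDG3 (1979 against 250, 2.95), an LTR element outside the OSC target list, and COPIA (2017 against 738, 1.44). GYPSY (1.18), MDG1 (0.97), QUASIMODO (0.96) and HMSBEAGLE (0.80) completed the 8 largest rises. DOC6 was lowest, at 443 against 885 (-0.99), followed by TLD2 (-0.56, from 25 and 23 reads), MARINER2 (-0.41) and HOBO (-0.41). Across the OSC target list the median was 0.45 (interval 0.40 to 0.49), 6 members were at least 1.5-fold higher, and 59 of 10000 random lists reached it. Across all transposons 12 were higher and 1 lower, with a median of -0.08.

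HP1a-KD gave the largest count of accessible transposons among the 4 knockdowns, with 30 at least 1.5-fold higher and none as much lower. They were led by DM297 (1489 RPKM, 2.97), COPIA (4265, 2.52), QUASIMODO (984, 2.48), Gypsy2 (316, 2.15), MDG3 (832, 1.71), INVADER4 (370, 1.58), GYPSY3 (69.2, 1.48) and STALKER4 (823, 1.44). BARI (-0.53), TLD2 (-0.46, from 25 reads in each column), HOBO (-0.41) and R2 (-0.40) were lowest. All 14 kept members of the OSC target list were higher, 12 at least 1.5-fold, with a median of 1.07 (interval 1.01 to 1.11), and 155 of 10000 random lists reached it. Relative to a median transposon of 0.21 the list stood at 0.85, and 22 transposons were higher and 4 lower.

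In Mael-KD, DM297 reached 11981 RPKM (5.97), close to its value in Piwi-KD, and GYPSY stood at 2917 (2.20). Gypsy2 (212, 1.58), MDG3 (668, 1.39), MDG1 (0.94), COPIA (0.90), QUASIMODO (0.63) and STALKER2 (0.59) followed, and BAGGINS1 (-0.63), HOBO (-0.60), G (-0.56) and DMRT1A (-0.54) were lowest. The median of the OSC target list was 0.33 (interval 0.30 to 0.38), 5 members were at least 1.5-fold higher, and 8 of 10000 random lists reached it. Relative to a median transposon of -0.23 the list stood at 0.57. Counts were 8 higher and 2 lower as deposited, and 11 and 0 relative to the median transposon. DM297 took 323818 of 4106936 reads in this column, which lowers the depth-scaled values of other transposons here too.

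Set against each other, Piwi-KD exceeded H1-KD at GTWIN (235 against 27.7 RPKM, log2 difference 2.85), DM297 (2.50), Gypsy2 (2.33), GYPSY (2.25), QUASIMODO (1.37), DM176 (1.27), DOC6 (1.19) and GYPSY5 (1.16). It lay below H1-KD at MDG3 (332 against 1979, -2.55), HMSBEAGLE (-1.06), STALKER3 (-0.83) and ZAM (-0.80). Of 10000 random lists none reached the median difference of the OSC target list, 0.47, or 0.67 relative to a median of -0.20. As for RNA, a list of reported Piwi targets is not independent evidence of this direction. Counts were 9 higher and 11 lower, and 11 and 5 relative to the median transposon.

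Mael-KD minus Piwi-KD was lowest at Gypsy2 (-3.73), GTWIN (-2.78), QUASIMODO (-1.70) and GYPSY (-1.23), with DM297 at -0.02. In that contrast 7 transposons were at least 1.5-fold lower and MDG3 (0.99) alone was as much higher. The next values were DMTOM1 (0.42), DIVER (0.38), Jockey (0.38), INVADER4 (0.37), STALKER3 (0.37), GYPSY6A (0.32) and BARI (0.32). HP1a-KD minus Piwi-KD was lowest at Gypsy2 (-3.16), DM297 (-3.02), GYPSY (-2.02) and GTWIN (-1.90), and highest at GYPSY3 (2.04), STALKER4 (1.71), INVADER4 (1.69), DMTOM1 (1.64), PROTOP_B (1.56), GYPSY6A (1.55), COPIA (1.51) and INVADER2 (1.47). Counts for HP1a-KD minus Piwi-KD were 34 higher and 4 lower, or 15 and 9 relative to a median of 0.45.

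The ATAC comparisons shared 1 control column. Between Piwi-KD and H1-KD 6 higher transposons were common, where independent lists would share 1.38, and the covariance was 0.528 against 0.003 for unchanged libraries (Spearman 0.52 against 0.56). Piwi-KD and Mael-KD shared 6 (0.92 for independent lists, covariance 0.698, Spearman 0.84 against 0.54), and Piwi-KD and HP1a-KD shared 11 (3.44 for independent lists, covariance 0.477, Spearman 0.51 against 0.56). For H1-KD and HP1a-KD the shared count was 10 (3.75 for independent lists, covariance 0.345, Spearman 0.72 against 0.54). Unchanged libraries, which differ by counting error alone, shared at most 0.023 transposons in any of these pairs.

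**Figure D3:**
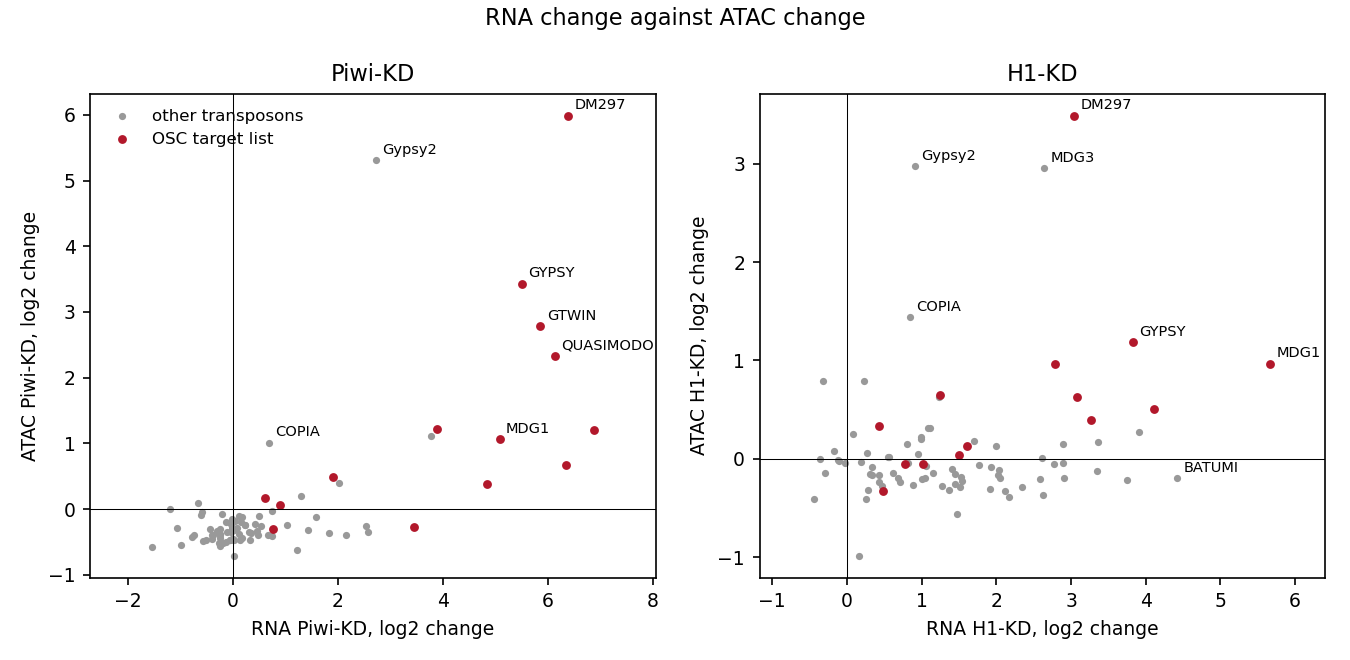
Log2 change of RNA (horizontal axis) against log2 change of ATAC signal (vertical axis) for the 88 transposons kept in both tables, in Piwi-KD (left) and H1-KD (right), with the OSC target list in red. DM297 lay highest on the ATAC axis in both panels (5.99 and 3.49), and BATUMI was high on the RNA axis in H1-KD (4.42) without a higher ATAC value.

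Transposons with higher RNA in Piwi-KD also tended to have higher ATAC signal, as GYPSY and DM297 did, with a Spearman correlation across 88 transposons of 0.53 (Pearson 0.70). The permutation p was 1e-05, the smallest that the 100000 permutations can give, and 4e-05 adjusted over the 4 planned correlations. In H1-KD the same relation was 0.11 (permutation p = 0.289, adjusted 0.289, Pearson 0.23), with MDG3 and DM297 high on both axes. ZAM and BATUMI were high in RNA, with ATAC changes of 0.50 and -0.20. H1 over input and ATAC signal in Piwi-KD were related at -0.34 across 87 transposons (permutation p = 0.00102, adjusted 0.00136, Pearson -0.60), which became -0.22 without input (adjusted permutation p = 0.0775). H1 and H3K9me3 over input in Piwi-KD were related at 0.37 across 93 transposons (permutation p = 0.00027, adjusted 0.00054, Pearson 0.70). They share input libraries, and without input the value was 0.14 (adjusted permutation p = 0.252). Unchanged libraries gave 0.53, which ranks counting error alone and is no threshold for the observed correlation. The covariance was 0.108 against 0.007 for unchanged libraries, and 3 transposons were lower in both, where independent lists would share 0.42 and unchanged libraries 0.05. All tests were two-sided, and transposons are not independent replicates.

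Small RNA bound to Piwi was compared between H1-KD and control to ask whether piRNA supply depends on H1. Small RNA of the DNA transposon BARI stood at 1006 RPM against 4.46 (log2 change 6.34), of the LTR element MICROPIA at 706 against 8.65 (5.41) and of ROO at 34352 against 5462 (2.65). DOC3 (3.44), INVADER2 (3.30), G5 (3.12), BEL (2.90) and INVADER6 (2.78, from 7 control reads) completed the 8 largest rises. For the OSC target list the median was -0.47 (interval -0.48 to -0.46), with TABOR lowest (4819 against 8227 RPM, -0.77) and GTWIN highest (49947 against 44194, 0.18), and no member passed 2-fold. STALKER3 (-0.74), GYPSY3 (-0.74) and GYPSY6A (-0.69) were the other 3 lowest.

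At least 2-fold higher were 32 of 96 transposons and none was as much lower. The median transposon was at 0.27, and relative to it 23 were higher and 3 lower and the OSC target list stood at -0.74, with 39 of 10000 random lists as low. The piRNA-rich list, whose members were selected on this same control library, had a median of -0.43, the mdg1 group -0.58, the gypsy group -0.26, the telomeric elements -0.26, the copia group -0.07, germline-dominant transposons 0.03, jockey-clade and I-clade non-LTR elements 0.26, DNA transposons 0.97, the BEL/Pao group 1.11 and rDNA and R elements 1.23. Germline-dominant transposons mark another cell type of the ovary, and 3 of their 10 kept members were at least 2-fold higher.

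**Figure D4:**
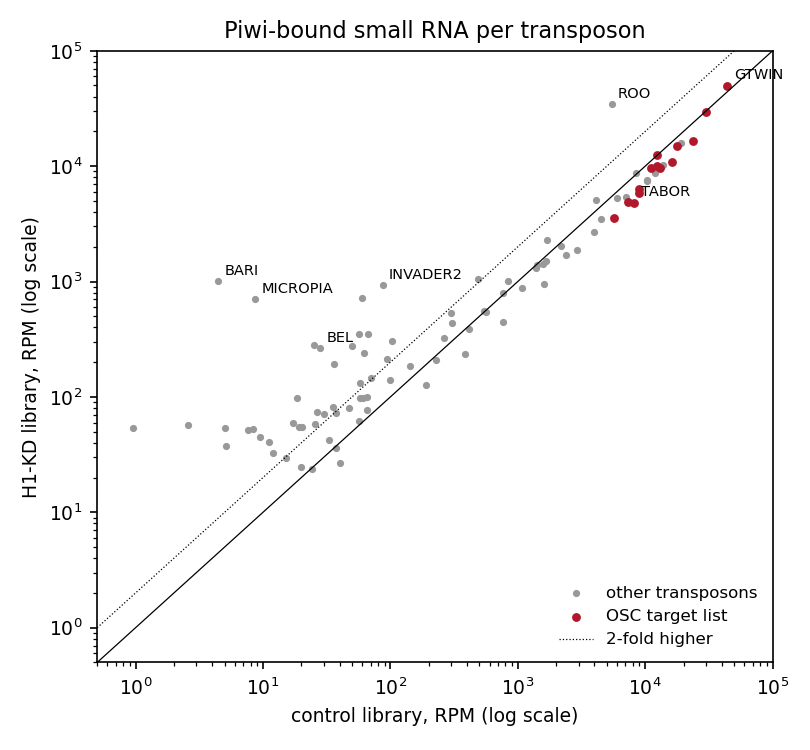
Piwi-bound small RNA in RPM in the H1-KD library (vertical axis) against the control library (horizontal axis), both logarithmic, with 1 point per kept transposon (96 points) and the OSC target list in red. The solid line marks equal values and the dotted line 2-fold higher values. The largest rises, BARI (6.34) and MICROPIA (5.41), stood under 10 RPM in the control, and ROO stood at 5462 RPM.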

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

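Apart from the limma counts, whose alternatives were chosen after seeing the data, all alternatives were fixed before the data were examined. The smaller and larger pseudocounts were 0.01 and 0.5 of the median nonzero value, no filter or the lower 50% left out replaced the filter, and changes were centred on the median transposon. Of 140 recomputed values of the 24 leading results, 97 kept their direction and stayed within the spread, interval or factor of 1.5 set for them, and the cause of the other 43 was not tested. Direction turned in 1 leading value, the HP1a ChIP list median in H1-KD, at -0.0592 when centred, and in 2 of 746 values of the 144 named changes past the fold threshold: RNA of DM176 in H1-KD (-0.18 when centred) and H1 at PROTOP_B in Mael-KD (0.0702 without input). Named changes below the threshold were not counted there, and some turn when centred, such as RNA of COPIA in H1-KD (-0.34).

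Centring changed the count of higher RNA in H1-KD to 24, the list medians to -0.23 for H1 in HP1a-KD, -0.87 for H3K9me3 in Piwi-KD and -0.74 for small RNA, and the count below H1-KD in the ATAC contrast of Piwi-KD to 5. With the larger pseudocount, list medians were -0.27 for H1 in HP1a-KD, -0.38 for H3K9me3 in Piwi-KD and -0.26 for HP1a in Piwi-KD, the ATAC contrast count was 6 and the small RNA count 18. With the stricter filter, the RNA H1-KD count was 31, list medians were -0.14 for H1 in Piwi-KD, -0.66 and -0.33 for H3K9me3 in Piwi-KD and H1-KD, the ATAC contrast count was 7 and the small RNA count 15. Fewer transposons enter these counts. With no filter, list medians were -0.36 for H3K9me3 in Piwi-KD, -0.26 for HP1a in Piwi-KD and -0.50 for small RNA. Without input they were -0.0814 and -0.28 for H1 in Mael-KD and HP1a-KD, -0.14 for H3K9me3 in H1-KD, and -0.23 and 0.20 for HP1a in Piwi-KD and H1-KD. Against the mean of 3 controls, H1 medians were -0.13 in Piwi-KD and -0.39 in HP1a-KD.

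For correlations, Pearson's r between RNA and ATAC in H1-KD was 0.23 and passed (adjusted permutation p 0.0311), while without input H1 against ATAC (-0.22) and H1 against H3K9me3 (0.14) in Piwi-KD did not. The limma count for Piwi-KD ranged from 0 to 23 when each control was left out in turn and was 0 without input. For Mael-KD it was 1 with each control left out, 3 with the smaller pseudocount and with no filter, and 0 with the stricter filter, when centred and without input. For HP1a-KD it ranged from 2 to 6 with a control left out, and was 7 with the stricter filter, 1 when centred and 0 without input.

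No paired analysis was possible because the ATAC table has 1 column per condition and each H1 ChIP knockdown forms 1 pair with a control. This limit holds for each knockdown taken alone. H1 changes were taken within these pairs, which share a sample number. A common effect over the H1 ChIP pairs, each of another knockdown, was not tested. The planned ATAC fits with a replicate block, on 2 groups alone, without trend and with replicates left out were not run. The single ATAC column per condition allowed none of them. Depth limits the short consensus sequences with few ChIP reads, such as POGON1 and GYPSY6A.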

Other observations

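All tests of explanations below were chosen after the results were seen.

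R1, R2, DMRT1A and DMRT1B, the kept members of the list of rDNA and R elements, are retrotransposons of which some insert into ribosomal DNA. Their median H3K9me3 change in H1-KD was 0.43, and 31 of 10000 random lists of 4 were as high. HP1a in H1-KD was at 0.35 (0.23 relative to the median transposon, 23 of 10000 lists), and H1 in HP1a-KD at 0.12 (0.23 relative to the median transposon, 15 of 10000 lists). The H1-KD values share input libraries. These comparisons are printed out of many combinations of list and comparison, and the counts of random lists are not adjusted for that choice. Relative to the median transposon, their median ATAC changes were -0.17 in Piwi-KD, -0.20 in H1-KD, -0.44 in HP1a-KD and -0.28 in Mael-KD, all against the same control column, so their common sign is not separate evidence from each knockdown.

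MDG3, outside the OSC target list, was 7.75-fold higher in ATAC signal in H1-KD, while its H3K9me3 change there was 0.19 and its RNA stood at 436 against 69.7 RPKM. In Piwi-KD its ATAC change was 0.40 and its RNA 285 RPKM. DOC6 had lower ATAC signal (-0.99) and lower H3K9me3 (-0.64) in H1-KD, with an RNA change of 0.17.

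The first pattern is the broad rise of transposon RNA in H1-KD, seen in 1 library. Reads from genomic DNA as the single source of all 56 rises are argued against by the RPKM gained per RPKM of input. Its 90th percentile among these transposons was 87.85 times its 10th (2.53 against 0.029). A small even addition of DNA reads, which would weigh most on transposons low in the control, is not excluded by it. A control library with low transposon values is argued against by the 33 of those 56 (58.9%) whose change in Piwi-KD, against the same control, was below 0.5 (median 0.16). A single scaling factor for the H1-KD library stays open for the breadth of the rise: relative to the median transposon 24 of the 56 (42.9%) stayed past 2-fold, and no replicate gives the spread between libraries. Derepression by loss of H1 stays open beside it.

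The second pattern is the rise of Piwi-bound small RNA of 32 transposons in H1-KD. The piRNA-rich list went from 29.6% to 24.97% of the library. Spread evenly over all other reads, the freed share allows a log2 change of 0.09111, below the median rise of 1.92. These values argue against freed reads spread evenly over the library. All transposons together went from 35.1% to 33.5% of the library, so other transposons did not take up the whole freed share. ROO alone went from 40406 to 239573 reads, of 7397276 and 6973985. What rise the part taken up by other transposons would allow was not estimated. Small RNA from ovarian germ cells stays open, although the line is described as free of them, since no germ-cell library was compared. Of 7 germline-dominant transposons under 100 RPM in the control, 4 rose at least 2-fold (BURDOCK, BEL, MAX and TRANSPAC). DIVER was 1.96-fold higher, HETA went from 8 to 12 reads and TAHRE from 5 to 1. These ratios have no pseudocount, and the filter had left out BURDOCK, HETA and TAHRE. With pseudocount, 32 of all 96 kept transposons rose at least 2-fold. BARI (4.46 RPM in the control) and MICROPIA (8.65), outside this list, also rose from low values. How often other low transposons rose was not counted, so the 4 do not single out germline-dominant transposons. More transcript of the same transposons also stays open: among transposons kept in both tables, RNA was at least 2-fold higher for 18 of 25 (72.0%) with more small RNA and for 31 of 56 others (55.4%), a difference of 16.64 percentage points (permutation p = 0.221), while with those the RNA filter left out the counts were 24 of 32 and 34 of 64 (permutation p = 0.0468). No biological explanation of this pattern was settled by these values.

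The third pattern is the gain of ATAC signal in Piwi-KD. DNA copies that raise input as much as ATAC signal are argued against by the ChIP input of sample 1. Among the 11 transposons that gained, the highest input change was 0.3458 and the lowest ATAC change 0.68 (medians 0.09 and 1.22). This input is not DNA of the ATAC samples. Copies that weigh more in ATAC than in input are not excluded by it, and input of DM297, the largest ATAC gain, was itself higher in Piwi-KD. One scaling factor for the column is argued against by the median change of all 96 transposons, -0.3194, which lay below the lowest gain by more than their interquartile range of 0.302. Open chromatin after loss of Piwi stays a hypothesis, from 1 column per condition.

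Input DNA of DM297 stood at 312 RPKM in Piwi-KD against 244 in its control (log2 change 0.35, interval 0.30 to 0.40), and another control input reached 301. Over all kept transposons the SD of input changes was 0.12 to 0.15, and 1 transposon passed 1.5-fold in each knockdown.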
